A study of Homo sapiens with 24 samples.

How the data were processed

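RNA of A2780 cells was sequenced from 12 libraries in 6 groups of 2: normoxia and hypoxia (1% oxygen, 5% CO2) at 6 hr, 48 hr and 6 days. Per the labels, cells grew in RPMI medium with 10 to 15% fetal bovine serum, RNA was taken with miRVANA, and 3 ug was depleted of ribosomal RNA with Ribominus. Libraries were made with the SOLiD Total RNA-Seq kit, barcoded one by one and pooled, and read for 75 bases in the forward direction on a 5500xl. Libraries 1 and 2 are normoxia and 3 and 4 hypoxia at 6 hr, 5 and 6 normoxia and 7 and 8 hypoxia at 48 hr, and 9 and 10 normoxia and 11 and 12 hypoxia at 6 days.

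The deposited values are RPKM per gene symbol and RPKM per precursor miRNA, 1 column per library. The submitters' processing notes list Partek 6.6 and genome build hg19 without saying what was done with each, and the aligner, the transcript models, the filters and the reads counted in the denominator of RPKM are not given in the sources used here. Each symbol occurs once. Of 22446 symbols, 18976 are current, 2461 are older names and 1009 have no match in the reference names. Coordinates are not given, because the reference at hand is on another assembly than the one in the notes. Low precursor values lie on steps set by the length of the precursor, and 873 of 939 precursors have a length in the reference. From these steps the reads per library were inferred, within 0.05 reads of whole numbers for 96.1 to 98.9% of the values used, those of up to 20 reads. Gene values were estimated by the submitters and give no counts, so no count model was used. For a precursor at 0 in both libraries of a group, a floor of 3 reads per library was set against the other group. Floors cover counting error only, and PCR copies are not independent molecules.

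Choices of groups, tests, lists, named genes and alternatives were made before the data were examined, apart from those said to be made after. RPKM as deposited was used with no further normalization. Genes and precursors with at least 1 RPKM in at least 2 of 12 libraries were tested, 11933 genes and 166 precursors, each table apart. The test was limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5) with 6 group means, an empirical Bayes estimate of the spread with an intensity trend, two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05 on adjusted p. The residual degrees of freedom were 6, with 5.08 more from the prior for genes and 6.14 for precursors. Hypoxia was compared with normoxia at each time, the effects of the 3 times were compared by contrasts in the same model, and normoxia at 48 hr and at 6 days was compared with normoxia at 6 hr. Hypoxia across times was tested with time and oxygen as additive terms. Calls shared between times were tested with Fisher's exact test, two-sided, adjusted over 6 tests, with p below 1e-300 set to that value before adjustment. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

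Gene lists were 33, written from general knowledge: HIF targets, oxygen sensing, glycolysis, dioxygenases, matrix, secreted factors, respiratory chain, TCA cycle, mitochondrial and cytosolic ribosome, ribosome biogenesis, DNA replication, mitosis, histones, DNA repair, p53, stress responses, heat shock, sterols, autophagy, mesenchymal transition, stemness, interferon, NF-kB, immediate-early genes, splicing, long RNAs, nucleotide synthesis, reference genes and markers of 4 other cell types. Of these, 30 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry were run beside it. A further 4 lists held precursor miRNAs. Lists overlap, so some genes count in several.

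Named genes were chosen by a rule: at each time the 6 highest and 6 lowest log2 fold changes among genes past the threshold with a mean of at least 2 RPKM in the higher group and no overlap between the libraries of both groups. To these were added 10 index genes, up to 4 past-threshold members of each list, the 5 highest and 5 lowest differences between times, the 4 highest and 4 lowest changes with time in normoxia, the 5 highest and 5 lowest precursors and 3 index precursors. The rule set beforehand also named the 2 members of highest level in lists where none passed. After the results were seen these were left unnamed, and such lists are given as counts. Short non-coding RNAs (names starting SNOR, SCARNA, RNU or MIR) were counted apart. No sample was left out.

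The procedure was tested on simulated data made from these libraries, with 200 of 11933 genes changed. Changes of log2 0.5, 1 and 2 were recovered in 53.8, 96.2 and 100% at 6 hr, with 9.09% of 176 calls false. The shares were 38.8, 98.8 and 97.5% at 48 hr with 6.88% of 160 calls false, and 37.5, 91.2 and 100% at 6 days with 4.03% of 149 calls false. Across times 99% of 200 changes of log2 1 were recovered, with 2.46% of calls false. For precursors at 6 days, changes of log2 1, 2 and 4 were recovered in 10, 60 and 100%, with 5.56% of 18 calls false. A list lowered by log2 0.5 was found at each time, with 1, 1 and 3 lists called at 6 hr, 48 hr and 6 days, of which 0, 0 and 1 were false, lists sharing a gene with the lowered one not being counted as false. Errors were drawn for each gene apart, so correlation between genes was not part of the simulation.

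Alternatives were offsets of 0.1 and 1, no minimum, a minimum of 5 RPKM, quantile normalization, centring each library on a trimmed mean (30% from each side) of its log2 ratios to the mean library, no intensity trend, the 4 libraries of a time alone, and each library left out in turn. Leaving out the libraries of 6 days, and trimmed-mean centring for the lists, were chosen after seeing the data.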

Results

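A2780 is an established human epithelial ovarian cancer cell line. The cells were kept in 1% oxygen (hypoxia) or at normal oxygen (normoxia) for 6 hr, 48 hr or 6 days, and their RNA was sequenced after depletion of ribosomal RNA. Each of the 6 groups had 2 libraries, 12 in all, and each library gave 2 tables: RPKM (reads per kilobase of transcript per M reads, M being 1e6) for 22446 gene symbols and for 939 precursor miRNAs, the hairpin transcripts that are cut into mature miRNAs. The 24 samples of the series are these 2 tables of the 12 libraries. The labels state no aim beyond testing hypoxia against normoxia at 3 times, so the questions below are how low oxygen changed the RNA at each time, whether the change differed between times, and what changed with time in normoxia alone.

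The read totals that the precursor values imply ran from 25.2 M reads (library 12, hypoxia at 6 days) to 51.8 M (library 1, normoxia at 6 hr). The other totals were 26.1, 38.3, 35.6, 40.7, 46.3, 34.9, 35.3, 29.8, 30.3 and 33.2 M for libraries 2 to 11. At 25.2 M reads, 1 read on a precursor of 90 bases is 0.442 RPKM, and at 51.8 M it is 0.214 RPKM. The 2 libraries of a group had Pearson r of 0.989 to 0.995 across the 11933 tested genes, which are not independent replicates. Libraries 1 and 2 stood furthest apart within a group, with a median absolute log2 difference of 0.20, against 0.09 to 0.13 in the other pairs. The first principal component held 63.6% of the variance and set the 4 libraries of 6 days apart from the other 8, and the second held 17.0% and set hypoxia apart from normoxia at each time.

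Levels below are means ± SD of the 2 libraries of a group, the hypoxia group first. Fold changes and adjusted p values of single genes come from limma with Benjamini-Hochberg adjustment over all genes tested, on log2(RPKM + 0.5), a scale that understates the fold of genes with little RNA. The largest changes named are among genes with a mean of at least 2 RPKM in a group and no overlap between the groups' libraries, short non-coding RNAs apart. Gene lists were tested with limma's camera. The labels do not say whether the libraries of a group came from separate cultures, so p values measure the spread between these libraries. Hypoxia calls grew from 428 genes at 6 hr to 1448 at 48 hr and 5039 at 6 days.

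**Figure D1:**
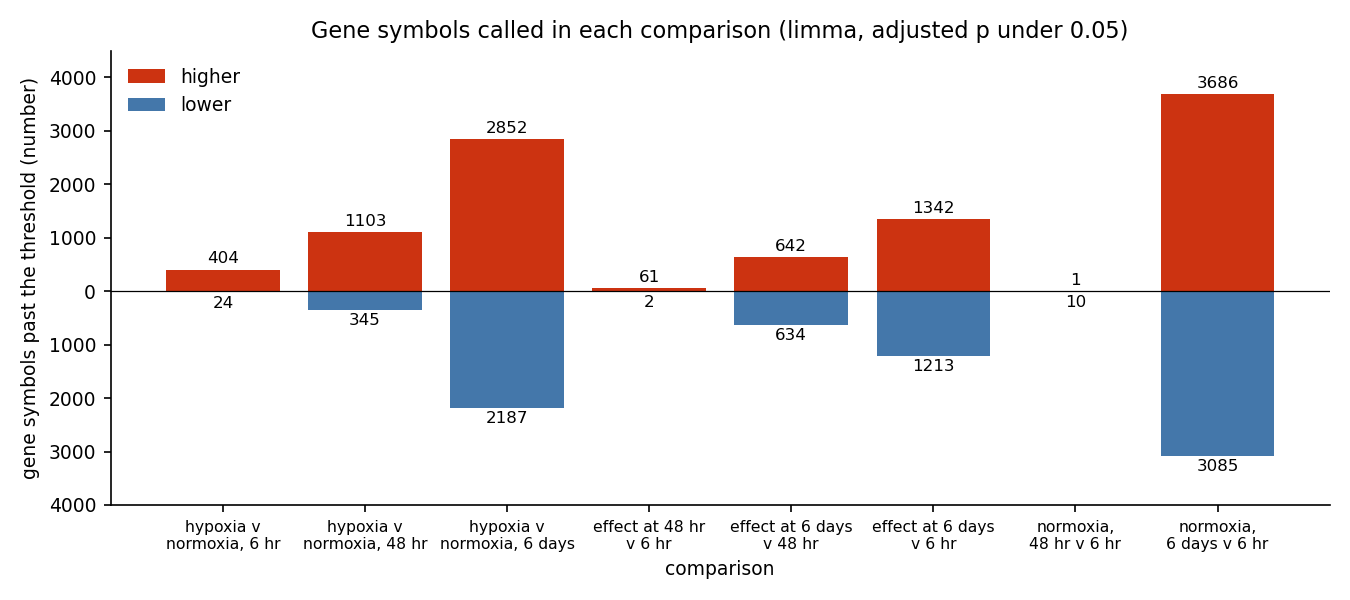
Number of gene symbols past the threshold in each comparison (vertical axis; higher above 0, lower below 0) for hypoxia against normoxia at 3 times, for the 3 differences of that effect between times, and for normoxia over time (limma, 11933 gene symbols). Hypoxia at 6 days and normoxia at 6 days against 6 hr had the most calls, 5039 and 6771.

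After 6 hr in 1% oxygen 41 of 53 targets of the hypoxia-inducible factors (HIF), 18 of 26 glycolysis genes, 7 of 21 oxygen-dependent dioxygenases and 5 of 16 secreted factors rose, and few genes fell. Of the 12 lists that passed camera with the preset correlation, HIF targets, glycolysis and matrix genes also passed with an estimated one. Of 11933 genes, 404 rose and 24 fell. On the log2(RPKM + 0.5) scale PFKFB4, which makes the glycolytic activator fructose 2,6-bisphosphate, rose most (10.5-fold, 17.4 ± 2.16 against 1.20 ± 0.0545 RPKM, adjusted p = 1.15e-08). PPFIA4, a liprin scaffold protein, rose 7.495-fold (6.67 ± 0.529 against 0.455 ± 0.0217 RPKM, adjusted p = 1.38e-07). ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose 6.69-fold (8.15 ± 0.837 against 0.794 ± 0.143 RPKM, adjusted p = 3.03e-07). INSIG2, which holds back the sterol sensor complex in the endoplasmic reticulum, rose 5.41-fold (10.9 ± 0.575 against 1.61 ± 0.0303 RPKM, adjusted p = 4.21e-07). The glycolytic aldolase ALDOC rose 5.198-fold (8.43 ± 0.343 against 1.23 ± 0.296 RPKM, adjusted p = 1.60e-06), and RIMKLA, an N-acetylaspartylglutamate synthetase, rose 4.68-fold (2.98 ± 0.0367 against 0.243 ± 0.0566 RPKM, adjusted p = 1.60e-06). At least 2-fold changes were found in 89 of the higher and 3 of the lower genes.

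HIF targets moved as a group at 6 hr: 41 of 53 rose, with 45 higher adjusted over the list alone, with a median log2 fold change of 1.16 (adjusted p = 6.78e-62). Among glycolysis genes, 18 of 26 rose, with 23 higher adjusted over the list alone (adjusted p = 4.36e-32). They include the glucose transporter SLC2A1 (4.50-fold, 18.9 ± 1.57 against 3.81 ± 0.0162 RPKM, adjusted p = 3.72e-07) and PDK1, the kinase that shuts off pyruvate dehydrogenase (3.03-fold, 11.3 ± 0.212 against 3.39 ± 0.284 RPKM, adjusted p = 1.60e-06). Of collagen modification and matrix genes, 7 of 20 rose, with 11 higher adjusted over the list alone (adjusted p = 2.81e-07), led by the lysyl hydroxylase PLOD2 (2.77-fold) and the prolyl hydroxylase subunits P4HA2 (2.38-fold) and P4HA1 (2.001-fold). Among angiogenic and secreted factors, 5 of 16 rose, with 5 higher adjusted over the list alone (adjusted p = 2.06e-05): ANGPTL4, the stanniocalcin STC2 (4.16-fold), the vasodilator adrenomedullin ADM (4.07-fold, 13.2 ± 0.351 against 2.87 ± 0.0942 RPKM, adjusted p = 2.28e-06), VEGFA (1.77-fold, 10.8 ± 0.970 against 5.93 ± 0.946 RPKM, adjusted p = 0.00165) and VEGFB. HIF targets, glycolysis, the matrix list and the secreted factors had adjusted p = 0.0144, 0.0491, 0.0144 and 0.0805 with an estimated correlation.

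Of dioxygenases of the Jumonji and TET families, which need oxygen to demethylate histones or oxidise DNA methylation, 7 of 21 rose, with 10 higher adjusted over the list alone (adjusted p = 1.36e-07). KDM3A rose 2.52-fold, TET1 2.39-fold and KDM4B 2.34-fold. Of immediate-early genes, 6 of 21 rose, with 10 higher and 2 lower adjusted over the list alone (adjusted p = 0.00263), with JUN at 2.40-fold, FOSL2 at 2.12-fold and ATF3 at 2.06-fold. Of mitophagy and autophagy genes, 3 of 22 rose, with 3 higher adjusted over the list alone (adjusted p = 0.0159): BNIP3L (4.42-fold), BNIP3 (3.86-fold, 64.7 ± 4.78 against 16.4 ± 0.108 RPKM, adjusted p = 1.60e-06) and ATG9A (1.55-fold). Of the integrated stress response, 4 of 33 rose, with 5 higher adjusted over the list alone (adjusted p = 0.0292), namely STC2, the mTORC1 inhibitor DDIT4 (4.01-fold), the lipoprotein receptor VLDLR (3.38-fold) and ATF3. The dioxygenases, immediate-early genes, mitophagy and autophagy and the integrated stress response had adjusted p = 0.0805, 0.0805, 0.596 and 0.676 with an estimated correlation. Of genes of the HIF machinery itself, 3 of 11 rose, with 3 higher adjusted over the list alone: the HIF prolyl hydroxylase EGLN1 (2.52-fold), the ubiquitin ligase SIAH2 (1.63-fold) and CITED2 (1.47-fold), while the list as a whole did not pass (adjusted p = 0.290). HIF1A itself stood at 17.6 ± 2.80 against 17.6 ± 5.24 RPKM (adjusted p = 0.968), CA9, a carbonic anhydrase, at 0.184 ± 0.0465 against 0.0124 ± 0.0176 RPKM (adjusted p = 0.171) and NDRG1 at 0.153 ± 0.0225 against 0.0718 ± 0.0489 RPKM (adjusted p = 0.461). EGLN3 (0.213 ± 0.00992 against 0.124 ± 0.0556 RPKM) and EPAS1 (0.184 ± 0.124 against 0.0949 ± 0.0295 RPKM) were below the minimum for testing.

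The genes that fell most at 6 hr were the histone genes HIST1H2AB, 1.73-fold (53.8 ± 4.67 against 93.2 ± 2.54 RPKM, adjusted p = 0.00458), and HIST1H2AD, 1.54-fold (59.5 ± 9.85 against 91.5 ± 0.144 RPKM, adjusted p = 0.0225), and TFRC. Near-identical copies can share the reads of histone genes. TFRC, the transferrin receptor that brings iron into the cell, fell 1.65-fold (55.4 ± 0.287 against 92.03 ± 14.7 RPKM, adjusted p = 0.00348). The next were FAM8A1 (1.47-fold), the p53-induced nuclease AEN (1.45-fold) and NUDT19 (1.42-fold). Ribosomal proteins (0.22, adjusted p = 0.000631) and the respiratory chain (0.16, adjusted p = 0.00138) passed camera with slightly higher medians, though only 2 of 78 (RPL41 among them) and 1 of 76 members (NDUFA13) rose. DNA replication (-0.08, adjusted p = 0.00816) and ribosome biogenesis (-0.07, adjusted p = 0.0159) passed with slightly lower medians and no single member past the threshold. Ribosomal proteins, the respiratory chain, DNA replication and ribosome biogenesis had adjusted p = 0.676, 0.676, 0.668 and 0.647 with an estimated correlation. The other 18 of the 30 lists tested by camera did not pass at 6 hr.

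Of the 428 calls at 6 hr, 94.4% were higher, against 76.1% after quantile normalization and 76.6% after centring each library on a trimmed mean. The number of calls rose to 836 without library 1 and fell to 181 without library 3, and to 278 with the 4 libraries of 6 hr fitted alone. Without 1 library the calls of HIST1H2AD, FAM8A1, AEN, NUDT19, ATG9A, CITED2, RPL41 and NDUFA13 ended (adjusted p 0.0510 to 0.316).

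**Figure D2:**
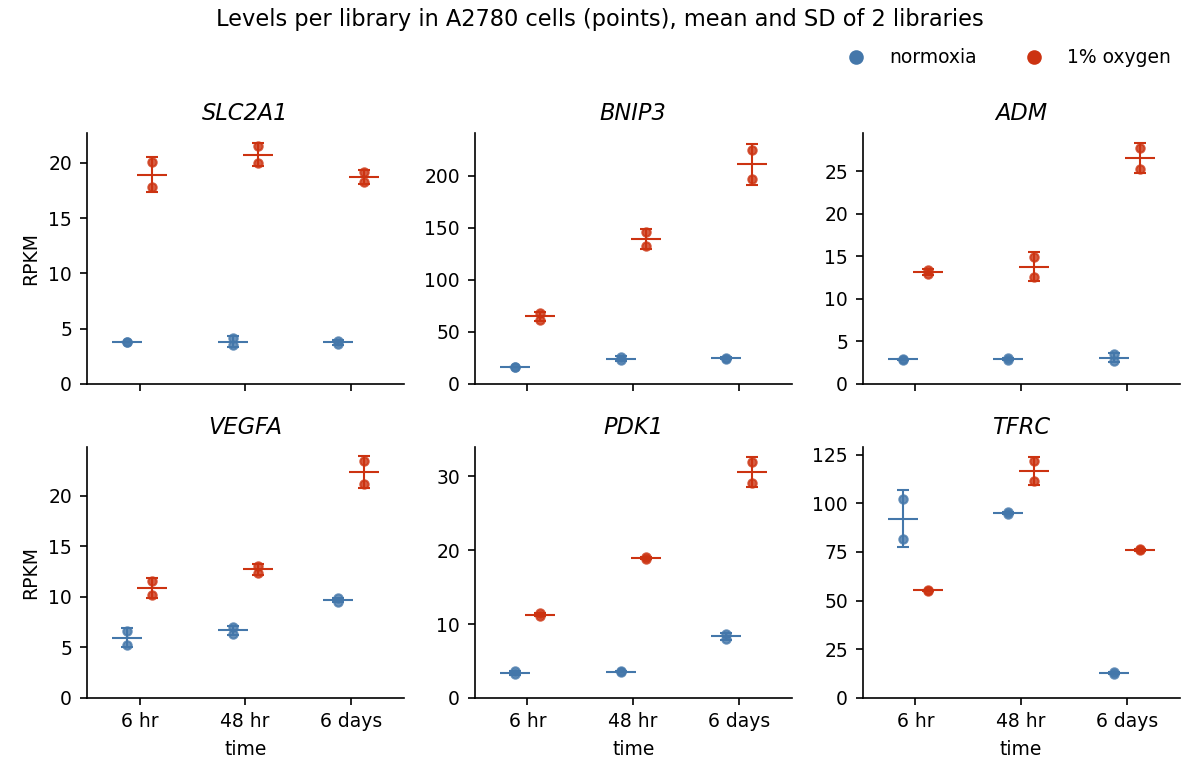
Level (RPKM, vertical axis) of 5 hypoxia index genes and of TFRC at 6 hr, 48 hr and 6 days (horizontal axis) in normoxia and 1% oxygen; points are the libraries, bars the mean and SD of 2 libraries. SLC2A1 lay between 17.8 and 21.5 RPKM in every hypoxia library, while TFRC was below normoxia at 6 hr (55.4 against 92.03 RPKM) and above it at 6 days (76.2 against 12.8 RPKM).

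After 48 hr of hypoxia 49 of 53 HIF targets, 24 of 26 glycolysis genes and 11 of 33 genes of the integrated stress response rose, and 8 of 40 ribosome biogenesis genes and 9 of 10 humanin-like transcripts fell. With an estimated correlation 5 of the 19 lists called by camera passed, and the stress response and ribosome biogenesis were not among them. Of 11933 genes, 1103 rose and 345 fell, 230 of the higher and 3 of the lower ones at least 2-fold. On the log2(RPKM + 0.5) scale PFKFB4 again rose most, 13.3-fold (20.6 ± 1.06 against 1.09 ± 0.0235 RPKM, adjusted p = 4.00e-09). ALDOC rose 12.3-fold (29.4 ± 2.60 against 1.93 ± 0.128 RPKM, adjusted p = 3.98e-08). BNIP3L, a mitochondrial receptor for autophagy, rose 10.3-fold (34.1 ± 3.28 against 2.84 ± 0.0887 RPKM, adjusted p = 7.88e-09). ANGPTL4 rose 8.81-fold (11.5 ± 0.671 against 0.866 ± 0.155 RPKM, adjusted p = 3.98e-08). CA9, a carbonic anhydrase of the cell surface, rose 8.26-fold (3.81 ± 0.951 against 0.0149 ± 0.00134 RPKM, adjusted p = 2.05e-07), and PPFIA4 rose 8.15-fold (7.27 ± 0.380 against 0.453 ± 0.0472 RPKM, adjusted p = 3.98e-08).

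HIF targets at 48 hr were almost all higher: 49 of 53 rose, with 51 higher adjusted over the list alone, at a median log2 fold change of 1.55 (adjusted p = 2.36e-59). Of glycolysis genes, 24 of 26 rose, with 24 higher adjusted over the list alone (adjusted p = 6.55e-31), among them the enolase ENO2 (5.11-fold) and SLC2A1 (4.93-fold, 20.7 ± 1.07 against 3.82 ± 0.471 RPKM, adjusted p = 8.89e-08). Of the other index genes, BNIP3 rose 5.69-fold (139 ± 9.23 against 24.1 ± 2.40 RPKM, adjusted p = 8.99e-08) and PDK1 4.81-fold (18.97 ± 0.158 against 3.55 ± 0.0350 RPKM, adjusted p = 3.98e-08). ADM rose 4.18-fold (13.8 ± 1.70 against 2.90 ± 0.118 RPKM, adjusted p = 7.27e-07), VEGFA 1.84-fold (12.7 ± 0.536 against 6.67 ± 0.471 RPKM, adjusted p = 0.000417) and NDRG1 1.69-fold (0.490 ± 0.00425 against 0.0849 ± 0.0187 RPKM, adjusted p = 0.00175). HIF1A stood at 14.4 ± 1.50 against 16.3 ± 2.84 RPKM (adjusted p = 0.621), and EGLN3 (0.298 ± 0.00479 against 0.0707 ± 0.0235 RPKM) and EPAS1 (0.221 ± 0.0331 against 0.0894 ± 0.0391 RPKM) were again below the minimum. Of angiogenic and secreted factors, 9 of 16 rose, with 10 higher adjusted over the list alone (adjusted p = 1.19e-07), with STC2 at 5.08-fold. Of collagen and matrix genes, 9 of 20 rose, with 10 higher and 1 lower adjusted over the list alone (adjusted p = 2.20e-05), with PLOD2 at 4.93-fold and the lysyl oxidase LOXL2 at 3.69-fold. HIF targets, glycolysis, the secreted factors and the matrix list had adjusted p = 0.0237, 0.0341, 0.0341 and 0.0269 with an estimated correlation.

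Of immediate-early genes, 11 of 21 rose, with 13 higher adjusted over the list alone at 48 hr (adjusted p = 1.46e-07), with the transcription factors ATF3 at 3.57-fold, FOSL2 at 3.13-fold and JUN at 2.85-fold. Of the integrated stress response, 11 of 33 rose, with 15 higher and 1 lower adjusted over the list alone (adjusted p = 7.65e-06): VLDLR rose 6.50-fold, DDIT4 5.74-fold and CHAC1, which degrades glutathione, 3.57-fold. Of Jumonji and TET dioxygenases, 11 of 21 rose, with 11 higher adjusted over the list alone (adjusted p = 2.88e-06), led by KDM3A (2.93-fold). Of mitophagy and autophagy genes, 6 of 22 rose, with 9 higher adjusted over the list alone (adjusted p = 0.000597). Immediate-early genes, the integrated stress response, the dioxygenases and mitophagy and autophagy had adjusted p = 0.0237, 0.296, 0.0983 and 0.233 with an estimated correlation. Of p53 targets, 8 of 27 rose and 1 fell, with 10 higher and 1 lower adjusted over the list alone (adjusted p = 0.0431), with SESN2 at 2.66-fold and the cell cycle inhibitor CDKN1A at 2.29-fold; the median of this list, 0.04, turned to -0.02 after quantile normalization. Fibroblast markers were present in these cells at 7 of 11 genes, and 4 of 7 rose, with 4 higher adjusted over the list alone (adjusted p = 0.0124): the proteoglycans LUM (2.15-fold) and DCN (1.45-fold), and TAGLN (1.58-fold) and ACTA2 (1.38-fold) of smooth muscle. Of mesenchymal transition genes, 3 of 15 rose, with 5 higher adjusted over the list alone (adjusted p = 0.0275), namely S100A4 (2.81-fold), CLDN7 and ITGA5, and of stemness genes NOTCH3 alone (2.21-fold; adjusted p = 0.0473 for the list). Targets of p53, fibroblast markers, mesenchymal transition and stemness had adjusted p = 0.440, 0.310, 0.233 and 0.296 with an estimated correlation. The long RNAs H19 (3.54-fold) and NEAT1 (2.77-fold), a scaffold of nuclear paraspeckles, rose.

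The lowest fold changes at 48 hr fell in the MTRNR2L family, nuclear copies of the mitochondrial 16S ribosomal RNA that can encode humanin-like peptides: 9 of 10 tested members fell. MTRNR2L2 fell 2.21-fold (568 ± 19.9 against 1260.0 ± 91.9 RPKM, adjusted p = 0.00831), and MTRNR2L6 (2.02-fold), MTRNR2L8 (1.97-fold), MTRNR2L1 (1.96-fold) and MTRNR2L10 (1.91-fold) followed, with PLA2G4A, the phospholipase that frees arachidonic acid (1.92-fold, 2.53 ± 0.0148 against 5.32 ± 0.238 RPKM, adjusted p = 0.000339). These copies can share reads, so their single values are uncertain. Of ribosome biogenesis genes, 8 of 40 fell, with 1 higher and 15 lower adjusted over the list alone (adjusted p = 3.17e-08), among them the processome proteins HEATR1 (1.45-fold) and UTP20 (1.45-fold). Of mitochondrial ribosome genes, 5 of 76 fell, with 1 lower adjusted over the list alone (adjusted p = 8.89e-06), led by MRPL3 (1.37-fold). Lists with lower medians and few calls were mitosis (ASPM fell; adjusted p = 2.20e-05), DNA replication (GINS1 and POLE2 fell, TK1 rose; adjusted p = 0.000597), homologous recombination, Fanconi and mismatch repair (FANCE fell; adjusted p = 0.00190), nucleotide and one-carbon synthesis (ATIC and UMPS fell; adjusted p = 0.0190) and replication histones (HIST1H2AB fell; adjusted p = 0.0431). Ribosome biogenesis, the mitochondrial ribosome, mitosis, DNA replication, DNA repair, nucleotide synthesis and replication histones had adjusted p = 0.134, 0.361, 0.304, 0.314, 0.296, 0.310 and 0.633 with an estimated correlation. The other 11 lists did not pass.

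At 48 hr 76.2% of the calls were higher, against 57.9% after quantile normalization and 60.6% after trimmed-mean centring. The 1448 calls fell to 811, 733, 619 and 804 without libraries 5, 6, 7 and 8. Without 1 library the calls of MTRNR2L2, MTRNR2L6, MTRNR2L8, MTRNR2L10, TAGLN, DCN, ACTA2, CLDN7, ASPM, GINS1, POLE2, TK1, FANCE, ATIC, UMPS and HIST1H2AB ended (adjusted p 0.0503 to 0.345).

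After 6 days of hypoxia 2852 genes were higher and 2187 lower. Higher than in normoxia of the same age were 52 of 53 HIF targets and 24 of 26 glycolysis genes, and lower were 33 of 40 genes of DNA replication, 36 of 50 replication histones, 20 of 27 sterol genes and 20 of 29 DNA repair genes. None of the 16 lists called by camera at 6 days passed with an estimated correlation. The largest rise was in NPPB, the precursor of B-type natriuretic peptide, which stood at 12.4 ± 1.82 RPKM in hypoxia and was listed at 0 in both normoxia libraries (adjusted p = 2.32e-08). CA9 rose 15.6-fold (8.16 ± 0.582 against 0.0535 ± 0.0146 RPKM, adjusted p = 2.32e-08), and the hormone stanniocalcin STC1 12-fold (5.75 ± 0.0375 against 0.0214 ± 0.00584 RPKM, adjusted p = 2.32e-08). LOX, which crosslinks collagen, rose 11.1-fold (10.1 ± 0.541 against 0.454 ± 0.0745 RPKM, adjusted p = 2.32e-08). PPP1R3C, which targets a phosphatase to glycogen, rose 10.2-fold (35.4 ± 2.11 against 3.05 ± 0.590 RPKM, adjusted p = 4.37e-08), and BNIP3 8.45-fold (211 ± 20.01 against 24.5 ± 1.09 RPKM, adjusted p = 2.32e-08). At least 2-fold changes were seen in 577 of the higher and 110 of the lower genes.

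Of the HIF targets, 52 of 53 rose, with 52 higher adjusted over the list alone at 6 days, at a median log2 fold change of 2.06 (adjusted p = 6.48e-34). Of glycolysis genes, 24 of 26 rose and 1 fell, with 24 higher and 2 lower adjusted over the list alone (adjusted p = 4.47e-17), with PFKFB4 at 6.27-fold, ENO2 at 5.86-fold and the glycogen branching enzyme GBE1 at 5.75-fold. Of the other index genes, ADM rose 7.59-fold (26.6 ± 1.73 against 3.09 ± 0.568 RPKM, adjusted p = 4.37e-08) and NDRG1 6.26-fold (4.38 ± 0.103 against 0.280 ± 0.0581 RPKM, adjusted p = 8.01e-08). SLC2A1 rose 4.51-fold (18.7 ± 0.624 against 3.75 ± 0.201 RPKM, adjusted p = 8.27e-08), PDK1 3.50-fold (30.6 ± 2.02 against 8.36 ± 0.483 RPKM, adjusted p = 1.16e-07) and VEGFA 2.24-fold (22.3 ± 1.59 against 9.68 ± 0.238 RPKM, adjusted p = 2.10e-05). HIF1A was at 18.2 ± 2.28 against 23.6 ± 0.317 RPKM (adjusted p = 0.136), EGLN3 at 0.677 ± 0.0962 against 0.0492 ± 0.0524 RPKM and EPAS1 at 0.617 ± 0.0310 against 0.135 ± 0.0259 RPKM, both below the minimum for testing. Of angiogenic and secreted factors, 10 of 16 rose and 1 fell, with 11 higher and 1 lower adjusted over the list alone (adjusted p = 0.000213). Of collagen and matrix genes, 10 of 20 rose and 4 fell, with 11 higher and 4 lower adjusted over the list alone (adjusted p = 0.00342), led after LOX by PLOD2 (6.47-fold) and P4HA2 (5.52-fold). HIF targets, glycolysis, the secreted factors and the matrix list had adjusted p = 0.103, 0.136, 0.136 and 0.136 with an estimated correlation. Of Jumonji and TET dioxygenases, 12 of 21 rose, with 13 higher adjusted over the list alone (adjusted p = 0.000102), with KDM3A at 4.38-fold. Of mitophagy and autophagy genes, 15 of 22 rose, with 15 higher adjusted over the list alone (adjusted p = 0.000336), with BNIP3L at 6.42-fold and GABARAPL1, a homologue of the autophagosome protein ATG8, at 2.16-fold. Of heat-shock genes, 7 of 17 rose, with 7 higher adjusted over the list alone (adjusted p = 0.00987), with the co-chaperone DNAJB1 at 2.27-fold and HSPA1A at 2.05-fold. The dioxygenases, mitophagy and autophagy and heat-shock genes had adjusted p = 0.143, 0.186 and 0.243 with an estimated correlation. In normoxia heat-shock genes had fallen by 6 days, with a median log2 fold change of -1.55 against 6 hr.

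DNA replication genes were lower at 6 days: 1 of 40 rose and 33 fell, with 1 higher and 33 lower adjusted over the list alone (adjusted p = 3.93e-11). RRM2, a subunit of ribonucleotide reductase, fell 1.98-fold (18.0 ± 0.780 against 36.1 ± 2.63 RPKM), the helicase subunit MCM7 1.91-fold and the helicase loader CDC45 1.90-fold. Of replication-dependent histones, 1 of 50 rose and 36 fell, with 1 higher and 37 lower adjusted over the list alone (adjusted p = 3.93e-11). HIST1H4K fell 3.31-fold (11.4 ± 2.35 against 38.4 ± 1.60 RPKM, adjusted p = 0.000108), HIST1H4I 3.10-fold (5.14 ± 1.95 against 16.5 ± 1.79 RPKM, adjusted p = 0.000111) and HIST1H2BJ 3.06-fold (112 ± 11.2 against 344 ± 17.2 RPKM, adjusted p = 6.52e-05), all among the genes that fell most. Near-identical histone copies can share reads. Summed over 63 histone genes, a set chosen after the values were seen, the level in normoxia was 6375, 8097.5 and 11322 RPKM at 6 hr, 48 hr and 6 days, and in hypoxia 5632, 7295 and 5849 RPKM. The lower value in hypoxia at 6 days thus goes with a normoxia level that had risen. Of homologous recombination, Fanconi and mismatch repair genes, 1 of 29 rose and 20 fell, with 1 higher and 22 lower adjusted over the list alone (adjusted p = 5.63e-07), with FANCI at 1.85-fold and the Bloom helicase BLM at 1.68-fold. Of nucleotide and one-carbon synthesis genes, 2 of 19 rose and 10 fell, with 2 higher and 12 lower adjusted over the list alone (adjusted p = 0.000336), with the purine enzymes PFAS at 2.51-fold and GART at 2.16-fold. DNA replication, replication histones, DNA repair and nucleotide synthesis had adjusted p = 0.136, 0.210, 0.136 and 0.188 with an estimated correlation. Of mitosis genes, 2 of 39 rose and 6 fell, with 3 lower adjusted over the list alone, and the list did not pass (adjusted p = 0.114).

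Sterol synthesis and uptake genes were lower as well: 2 of 27 rose and 20 fell, with 2 higher and 21 lower adjusted over the list alone (adjusted p = 7.36e-07). The farnesyl diphosphate synthase FDPS fell 2.77-fold (23.9 ± 3.06 against 66.7 ± 0.425 RPKM), the acetyl-CoA carboxylase ACACA 2.07-fold and the sterol carrier STARD4 1.99-fold, whereas INSIG2, which restrains this pathway, rose 4.97-fold. Mitochondrial lists had lower medians. In the mitochondrial ribosome 1 of 76 rose and 29 fell, with 1 higher and 28 lower adjusted over the list alone (adjusted p = 3.29e-07). In the TCA cycle 1 of 21 rose and 10 fell, with 1 higher and 12 lower adjusted over the list alone (adjusted p = 0.000508), and in the respiratory chain 5 of 76 rose and 25 fell, with 5 higher and 25 lower adjusted over the list alone (adjusted p = 0.00415). The sterol genes, the mitochondrial ribosome, the TCA cycle and the respiratory chain had adjusted p = 0.136, 0.325, 0.324 and 0.595 with an estimated correlation. ATP5G1 (2.34-fold) and ATP5D (2.24-fold) of ATP synthase and SDHB (1.76-fold) of succinate dehydrogenase fell, and NDUFB8 of complex I rose 2.09-fold. Of ribosome biogenesis genes, 3 of 40 rose and 20 fell, with 3 higher and 21 lower adjusted over the list alone (adjusted p = 0.000336), with the rRNA processing factor BOP1 at 2-fold. All 10 MTRNR2L members fell, led by MTRNR2L2 at 3.20-fold (407 ± 115 against 1283 ± 160.2 RPKM, adjusted p = 0.000252) and MTRNR2L8 at 3.05-fold (932 ± 184 against 2813 ± 67.0 RPKM, adjusted p = 0.000151). SFXN2, a mitochondrial carrier of the sideroflexin family, fell 3.19-fold (0.392 ± 0.0277 against 2.35 ± 0.0716 RPKM, adjusted p = 1.91e-06). Ribosome biogenesis had adjusted p = 0.243 with an estimated correlation.

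The remaining lists did not pass camera at 6 days. Of splicing factors, 4 of 31 rose and 12 fell, with 4 higher and 12 lower adjusted over the list alone, with the kinase CLK3 2.88-fold higher and SRSF7 1.92-fold lower. Of immediate-early genes, 11 of 21 rose and 4 fell, with 11 higher and 4 lower adjusted over the list alone. Of the integrated stress response, 13 of 33 rose and 6 fell, with 16 higher and 7 lower adjusted over the list alone. Of p53 targets, 9 of 27 rose and 6 fell, with 9 higher and 7 lower adjusted over the list alone. Of interferon genes, 6 of 24 rose and 7 fell, with 6 higher and 8 lower adjusted over the list alone. Of long non-coding RNAs, 4 of 21 rose and 6 fell, with 4 higher and 6 lower adjusted over the list alone. Of the HIF machinery, 5 of 11 rose and 1 fell, with 5 higher and 1 lower adjusted over the list alone. Of mesenchymal transition genes, 4 of 15 rose and 1 fell, with 4 higher and 1 lower adjusted over the list alone. Of stemness genes, 4 of 10 rose and 2 fell, with 4 higher and 2 lower adjusted over the list alone. Of NF-kB genes, 3 of 7 rose and 3 fell, with 3 higher and 3 lower adjusted over the list alone. Of fibroblast markers, 4 of 7 rose and 1 fell, with 4 higher and 1 lower adjusted over the list alone. Of ribosomal proteins, 1 of 78 rose and 4 fell. The lower calls of RPL4, RPL8 and RPS14 ended without 1 library (adjusted p 0.0501 to 0.287). Among long RNAs H19 rose 5.10-fold, among stemness genes HEY1 rose 3.70-fold and KLF4 3.24-fold, and among fibroblast markers POSTN fell 1.77-fold. In the housekeeping list, 4 of 16 rose and 3 fell, with 4 higher and 3 lower adjusted over the list alone: TFRC rose 5.76-fold (76.2 ± 0.547 against 12.8 ± 0.502 RPKM, adjusted p = 6.20e-08), PGK1 3.96-fold and GAPDH 2.55-fold. Markers of other cell types were mostly below the minimum: 1 of 12 leukocyte markers was tested (CORO1A, lower by 1.91-fold), 1 of 10 endothelial markers (ESAM, higher by 2.78-fold) and 4 of 13 epithelial and keratinocyte markers (MUC1 rose 2.12-fold).

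Short non-coding RNAs, counted apart, were higher in hypoxia at 6 days: 217 of 495 rose and 9 fell, with a median log2 fold change of 0.73, against 0.11 at 48 hr and -0.20 at 6 hr. Of SNORD genes, C/D-box guides of ribosomal RNA methylation, 110 of 213 rose and 1 fell, and of SNORA genes, guides of pseudouridylation, 39 of 99 rose. The summed level of SNORD genes was 392710 and 367800 RPKM in the normoxia and 534530 and 479000 RPKM in the hypoxia libraries of 6 days. Libraries of 1 group stood as far apart: 463310 and 345490 RPKM in libraries 1 and 2, and 468190 and 315730 RPKM in libraries 5 and 6. After quantile normalization the median dropped from 0.84 to 0.41 for SNORD, from 0.54 to 0.10 for SNORA and from 0.70 to 0.43 for SCARNA genes.

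At 6 days 56.6% of the 5039 calls were higher, against 45.3% after quantile normalization and 46.5% after trimmed-mean centring. Limma's fry, which does not compare a list with other genes, called 22 lists at 6 days, 13 higher and 9 lower. At 48 hr it called 19, 16 higher and 3 lower, where camera called 7 lower. At 6 hr it called 10, all higher, so camera's lower lists of that time, DNA replication and ribosome biogenesis, were not called lower by fry. Lists called by both in the same direction were 8 of camera's 12 at 6 hr, 15 of 19 at 48 hr and 15 of 16 at 6 days.

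**Figure D3:**
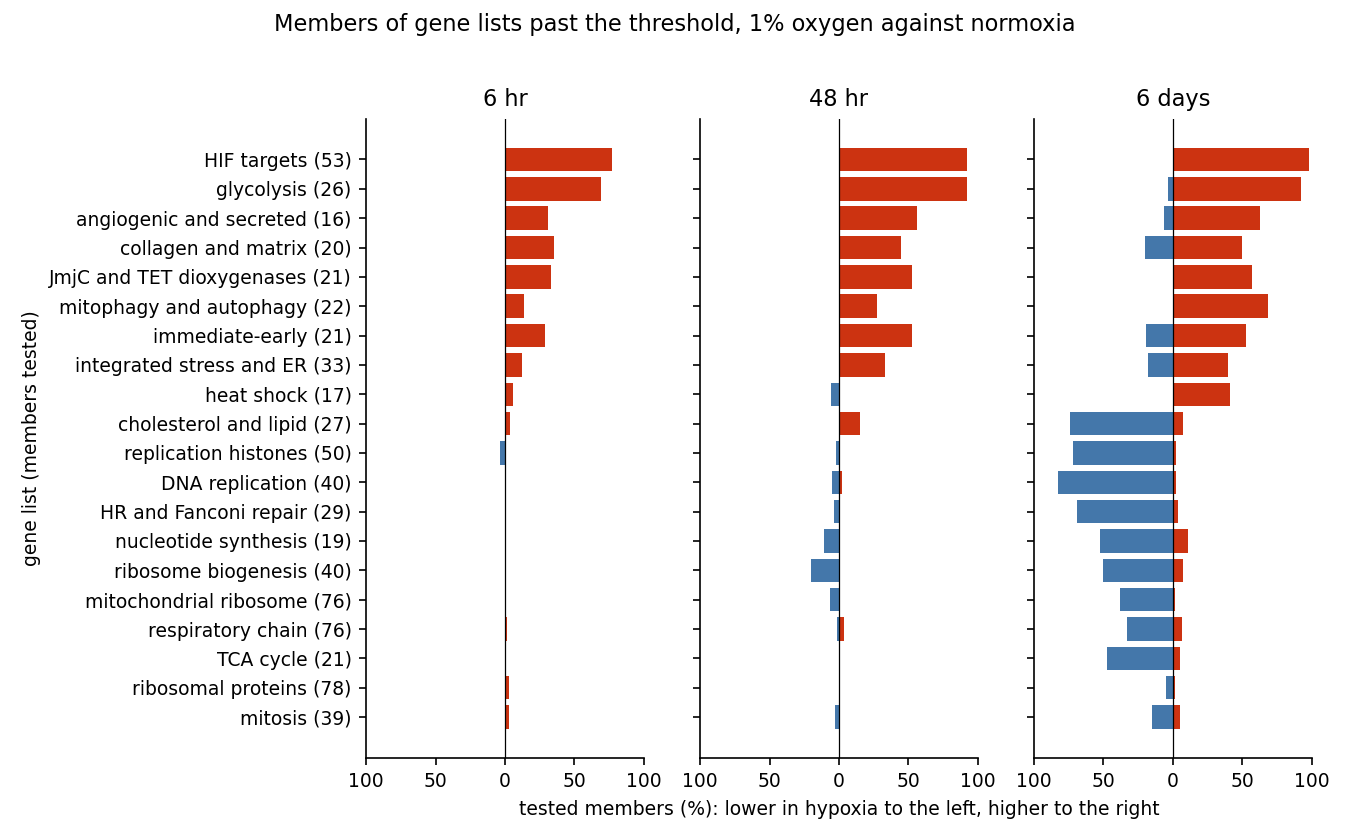
Share of the tested members of 20 gene lists that were past the threshold (horizontal axis, percent; higher in hypoxia to the right, lower to the left) at 6 hr, 48 hr and 6 days (limma, adjusted over all genes). Bars of HIF targets cover 41, 49 and 52 of 53 genes, and lower members of DNA replication 33 of 40 at 6 days.

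The hypoxia effect differed between times most between 6 days and 6 hr. The signed difference, the later minus the earlier log2 fold change, was called above 0 in 61 genes and below 0 in 2 from 6 hr to 48 hr. From 48 hr to 6 days it was above 0 in 642 and below 0 in 634, and from 6 hr to 6 days above 0 in 1342 and below 0 in 1213 (limma's test of the difference). A difference below 0 can be a weaker rise or a stronger fall. Without library 1 the calls from 6 hr to 48 hr were less one-sided. The highest difference from 6 hr to 48 hr was in TXNIP, an inhibitor of thioredoxin and glucose uptake. Its log2 fold change was 0.02 at 6 hr and 2.75 at 48 hr (difference 2.73, adjusted p = 0.000353). Next were CA9 (2.63, adjusted p = 0.000353), NPPB (2.03, adjusted p = 0.00437), the arrestin-like ARRDC4 (1.66, adjusted p = 0.000599) and KISS1R, the kisspeptin receptor (1.52, adjusted p = 0.00433). PLA2G4A had the lowest difference (-0.88, adjusted p = 0.0497), its log2 fold change being -0.07 at 6 hr and -0.94 at 48 hr.

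From 48 hr to 6 days the difference was highest in STC1 (log2 fold change 0.53 at 48 hr and 3.58 at 6 days; difference 3.05, adjusted p = 1.65e-05), NPPB (2.48, adjusted p = 0.000592), TFRC (2.23, adjusted p = 7.06e-05), the natriuretic peptide clearance receptor NPR3 (1.99, adjusted p = 0.000827) and LOX (1.94, adjusted p = 0.000419). It was lowest in DDIT4 (2.52 at 48 hr and 0.49 at 6 days; difference -2.03, adjusted p = 0.000284), CHAC1 (-1.92, adjusted p = 0.000575), HIST1H4I (0.06 at 48 hr and -1.63 at 6 days; difference -1.69, adjusted p = 0.00671), TXNIP (-1.54, adjusted p = 0.00214) and ARHGAP4 (-1.54, adjusted p = 0.00124). DDIT4 and CHAC1 belong to the integrated stress response, of which 12 of 33 members had a difference called below 0 and 3 above 0 (adjusted p = 0.00262). Sterol genes (13 of 27 called below 0; adjusted p = 3.91e-11), replication histones (17 of 50; adjusted p = 3.91e-11) and DNA replication (10 of 40; adjusted p = 3.69e-08) moved down over the same interval, to lower medians in hypoxia than in normoxia at 6 days. The integrated stress response, the sterol genes, replication histones and DNA replication had adjusted p = 0.620, 0.197, 0.403 and 0.403 with an estimated correlation. DNA repair (adjusted p = 0.000198), the respiratory chain (adjusted p = 0.00383), the mitochondrial ribosome (adjusted p = 0.00891), nucleotide synthesis (adjusted p = 0.00891) and the TCA cycle (adjusted p = 0.0114) passed in the same direction. DNA repair, the respiratory chain, the mitochondrial ribosome, nucleotide synthesis and the TCA cycle had adjusted p = 0.403, 0.650, 0.687, 0.471 and 0.650 with an estimated correlation. Heat-shock genes (5 of 17 called above 0; adjusted p = 6.50e-05) and HIF targets (16 of 53 above and 6 below; adjusted p = 0.0218) moved up. Heat-shock genes and HIF targets had adjusted p = 0.344 and 0.650 with an estimated correlation. These are differences of the effect, and normoxia changed as well. In normoxia the median log2 fold change from 6 hr to 6 days was -1.55 for heat-shock genes and 1.18 for the integrated stress response. From 6 hr to 48 hr it was 0.12 and 0.17. The difference above 0 of heat-shock genes thus goes with a normoxia level that had fallen. That below 0 of the stress response goes with a normoxia level that had risen.

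From 6 hr to 6 days the highest differences were in NPPB (4.50, adjusted p = 3.31e-06), STC1 (3.56, adjusted p = 1.93e-06), CA9 (3.55, adjusted p = 7.40e-06), TFRC (3.24, adjusted p = 1.93e-06) and LOX (2.92, adjusted p = 7.95e-06). The lowest were in HIST1H4I (-2.40, adjusted p = 0.000574) and in MTRNR2L7 (-2.20), MTRNR2L10 (-2.06), MTRNR2L6 (-1.95) and MTRNR2L2 (-1.94), all 10 members of that family being past the threshold. Among the index genes, NDRG1 (2.45, adjusted p = 2.34e-05), BNIP3 (1.13, adjusted p = 0.00111) and ADM (0.90, adjusted p = 0.00471) had a larger effect at 6 days than at 6 hr. The difference was 0.00 for SLC2A1 (adjusted p = 0.986), 0.21 for PDK1 (adjusted p = 0.252), 0.34 for VEGFA (adjusted p = 0.153) and -0.40 for HIF1A (adjusted p = 0.315). For NPPB these differences rest on a normoxia group listed at 0 at 6 days and depend on the offset of 0.5. Those of CA9, STC1 and NDRG1, with mean normoxia levels below 0.3 RPKM, depend on it as well.

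The counts moved when 1 library was left out: for 48 hr against 6 hr they were 110, 29, 19, 29, 26 and 11 without libraries 1, 3, 4, 5, 6 and 7. For 6 days against 48 hr the 1276 calls became 2152, 2154, 612, 548, 513, 365, 547, 480, 630 and 496 without libraries 1, 2 and 5 to 12, and 2479 after quantile normalization; for 6 days against 6 hr the 2555 became 1560, 1645, 1531, 1685 and 1498 without libraries 3, 9, 10, 11 and 12.

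Genes higher at one time tended to be higher at another. Of the 404 genes higher at 6 hr, 344 were higher at 48 hr (37.3 if the lists were independent; odds ratio 81.3, two-sided Fisher's exact test adjusted p below 3e-300) and 347 at 6 days (odds ratio 21.9, adjusted p = 2.53e-159). Of the 1103 genes higher at 48 hr, 840 were higher at 6 days (odds ratio 13.99, adjusted p below 3e-300), and of the 345 lower genes 222 were lower at 6 days (odds ratio 8.84, adjusted p = 7.44e-82). Of the 24 genes lower at 6 hr, 5 were lower at 48 hr (odds ratio 8.95, Fisher's exact adjusted p = 0.000636) and 8 at 6 days (odds ratio 2.23, Fisher's exact adjusted p = 0.0656), where 7 were higher. From 48 hr to 6 days 42 of the 1103 higher genes were lower and 8 of the 345 lower genes were higher, and from 6 hr to 6 days 9 of the 404 higher genes were lower. At all 3 times 320 genes were higher and 5 lower. The 3 times share no library, but 1 estimate of each gene's spread, from all 12 libraries, served all 3 comparisons. Calls were therefore not independent between times, which the expected count and the Fisher p values do not take into account. Fold changes across genes, which are not independent, had Pearson r of 0.57 between 6 hr and 48 hr, 0.62 between 48 hr and 6 days and 0.31 between 6 hr and 6 days. Shared calls in the same direction fell from 349 to 168 between 6 hr and 48 hr and from 355 to 170 between 6 hr and 6 days without library 3, and from 1062 to 661, 604, 518 and 656 between 48 hr and 6 days without libraries 5, 6, 7 and 8.

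Across the 3 times, with 6 hypoxia against 6 normoxia libraries and time as a term, 1830 genes were higher and 851 lower. The index genes PDK1 (log2 fold change 1.89, adjusted p = 5.39e-08), SLC2A1 (2.22, adjusted p = 1.95e-10) and BNIP3 (2.51, adjusted p = 1.81e-07) were higher. So were ADM (2.34, adjusted p = 1.81e-07), VEGFA (0.96, adjusted p = 3.24e-06), CA9 (2.48, adjusted p = 0.00162) and NDRG1 (1.20, adjusted p = 0.0147). HIF1A was at -0.17 (adjusted p = 0.294). Of these calls 68.3% were higher, against 43.7% after quantile normalization and 48.3% after trimmed-mean centring; without the libraries of 6 days, a choice made after the data were seen, 988 genes were higher and 202 lower.

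Normoxia at 6 days differed from normoxia at 6 hr in more genes than hypoxia from normoxia at 6 days: 3686 were higher and 3085 lower. The labels do not say whether cultures or library preparation also differed between these times, so such differences cannot be told apart from time. Of the integrated stress response 24 of 33 genes were higher at 6 days. Lower were 15 of 17 heat-shock, 36 of 40 ribosome biogenesis and 34 of 40 DNA replication genes. None of these lists passed with an estimated correlation. On the log2(RPKM + 0.5) scale CHAC1 rose most, 14.7-fold (23.9 ± 2.75 against 1.16 ± 0.0264 RPKM, adjusted p = 1.58e-08). The signalling adaptor BEX2 rose 11.6-fold (24.3 ± 1.44 against 1.66 ± 0.397 RPKM, adjusted p = 1.89e-08), the stress transcription factor DDIT3 11.5-fold (48.6 ± 1.48 against 3.78 ± 0.101 RPKM, adjusted p = 8.07e-09) and the asparagine synthetase ASNS 11.01-fold (70.9 ± 8.15 against 6.24 ± 2.72 RPKM, adjusted p = 4.96e-07). The chaperone HSPA8 fell most, 9.84-fold (95.3 ± 2.29 against 952 ± 191 RPKM, adjusted p = 1.01e-07). Small NF90-associated RNAs followed, with SNAR-D at 9.01-fold (12.5 ± 2.04 against 117 ± 13.0 RPKM, adjusted p = 5.47e-08) and SNAR-A1 and SNAR-A2 each at 8.46-fold (57.7 ± 1.12 against 497 ± 106 RPKM, adjusted p = 7.23e-07). All 27 SNAR members were lower, and near-identical copies can share reads. TFRC fell 6.90-fold (12.8 ± 0.502 against 92.03 ± 14.7 RPKM, adjusted p = 2.92e-08).

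Of the integrated stress response, 24 of 33 rose and 5 fell, with 24 higher and 6 lower adjusted over the list alone with time in normoxia (adjusted p = 4.60e-07). Of heat-shock genes, 15 of 17 fell, with 16 lower adjusted over the list alone (adjusted p = 2.19e-09), with HSPA1B at 4.44-fold and the mitochondrial chaperonin HSPE1 at 4.24-fold. Of ribosome biogenesis genes, 36 of 40 fell, with 36 lower adjusted over the list alone (adjusted p = 1.33e-13), with RRS1 at 4.14-fold. Of DNA replication genes, 34 of 40 fell, with 35 lower adjusted over the list alone (adjusted p = 6.48e-11), with cyclins CCNE2 at 3.27-fold and CCNE1 at 2.88-fold. The integrated stress response, heat-shock genes, ribosome biogenesis and DNA replication had adjusted p = 0.425, 0.100, 0.100 and 0.234 with an estimated correlation. Camera also called replication histones (adjusted p = 2.71e-05), ribosomal proteins (adjusted p = 0.000965), mitophagy and autophagy (adjusted p = 0.00743) and dioxygenases (adjusted p = 0.0290) higher. It called splicing factors (adjusted p = 0.000257), the mitochondrial ribosome (adjusted p = 0.00232) and nucleotide synthesis (adjusted p = 0.0127) lower, and none of these 7 passed with an estimated correlation. HIF targets moved without low oxygen as well: 28 of 53 rose and 8 fell, with 29 higher and 8 lower adjusted over the list alone (adjusted p = 0.00135), with DDIT4 at 8.80-fold, VLDLR at 5.42-fold and ALDOC at 5.33-fold. HIF targets had adjusted p = 0.574 with an estimated correlation. DDIT4 and VLDLR are also members of the integrated stress response list, which rose in the same comparison. The median log2 fold change was 0.43 for HIF targets and -0.12 for glycolysis genes.

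Between 48 hr and 6 hr of normoxia 1 gene, a miRNA gene, was higher and 10 were lower. Short non-coding RNAs made up 8 of the lower ones, and the others were the collagenase MMP1 (2.04-fold, 47.0 ± 0.564 against 96.8 ± 14.8 RPKM, adjusted p = 0.0128) and the metallothionein MT1F (3.07-fold, 0.502 ± 0.156 against 2.56 ± 0.183 RPKM, adjusted p = 0.0248). That count was 1310 (1166 higher and 144 lower) without library 1, 6 without library 2, 24 without library 3 and 24 without library 4, and 31 with a minimum of 5 RPKM, and the calls of MMP1 and MT1F ended without 1 library (adjusted p 0.0505 to 0.181).

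Precursor miRNAs were measured with few reads: 166 of 939 reached the minimum for testing. The precursor of miR-210, the miRNA most often tied to hypoxia, had 9 and 8 reads in hypoxia and 2 and 2 in normoxia at 6 hr (adjusted p = 0.673), 30 and 28 against 0 and 0 at 48 hr, and 39 and 25 against 0 and 2 at 6 days. At 48 hr hsa-mir-210 stood at 7.51 ± 0.432 RPKM and was at least 11.9-fold higher than a floor of 3 reads per normoxia library (adjusted p = 0.000630). It was the only precursor called at 48 hr. At 6 days it stood at 9.86 ± 1.17 against 0.3002 ± 0.425 RPKM (adjusted p = 0.00107). At 6 hr limma called 0 precursors, with 10 at an unadjusted p under 0.05. Among gene symbols, measured in the same libraries, MIR210 was called higher in hypoxia at each of the 3 times, 6 hr included.

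At 6 days 18 precursors were higher in hypoxia and 0 lower. Of 155 tested gene symbols starting MIR, from the same libraries, 52 were higher and 8 lower. Among the precursors, the next after hsa-mir-210 was hsa-mir-182, 6.13-fold (8.67 ± 1.03 against 1.06 ± 0.630 RPKM, adjusted p = 0.00891). Listed at 0 in normoxia, hsa-mir-30b stood at 2.61 ± 0.783 RPKM, at least 2.30-fold above the floor of 3 reads per library (adjusted p = 0.00891). Also listed at 0 in normoxia, hsa-mir-29b-2 stood at 2.41 ± 1.33 RPKM, at least 1.96-fold above that floor (adjusted p = 0.0263). The precursor hsa-mir-30d rose 5.24-fold (14.6 ± 1.81 against 2.38 ± 0.0253 RPKM, adjusted p = 0.0371). The precursor of miR-21 was at 5.42 ± 1.04 against 6.40 ± 1.47 RPKM at 6 hr (adjusted p = 0.989), 10.1 ± 2.43 against 3.48 ± 2.80 RPKM at 48 hr (adjusted p = 0.255) and 30.7 ± 16.9 against 5.32 ± 1.04 RPKM at 6 days (adjusted p = 0.0240). The precursor of miR-675, which is cut from H19, was at 2.62 ± 1.19 against 3.81 ± 3.51 RPKM at 6 hr (adjusted p = 0.989), 4.87 ± 0.233 against 1.22 ± 0.780 RPKM at 48 hr (adjusted p = 0.304) and 4.86 ± 0.714 against 0.908 ± 0.635 RPKM at 6 days (adjusted p = 0.0517). Of 21 tested precursors of a fixed list of hypoxia-responsive miRNAs, 5 rose at 6 days over all precursors and 15 were higher adjusted over the list alone; they were hsa-mir-210, hsa-mir-21, hsa-mir-193b, hsa-mir-23a and hsa-mir-30d. Of 10 let-7 precursors hsa-let-7a-2 rose (1 higher adjusted over the list alone), and the 10 tested precursors of the miR-17-92 clusters did not pass (median log2 fold change 0.75). Of the H19 and IGF2 list only hsa-mir-675 was tested, so adjustment over the list alone changed nothing. Its unadjusted p from limma was under 0.05 at 48 hr and at 6 days. Adjusted over all precursors it passed at neither time. Across times 4 precursors were higher, and limma's tests of differences between times called 0, with 19, 13 and 44 at an unadjusted p under 0.05 for 48 hr against 6 hr, 6 days against 48 hr and 6 days against 6 hr.

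The median log2 fold change of all 166 precursors was -0.10 at 6 hr, 0.30 at 48 hr and 0.74 at 6 days, and trimmed-mean centring, which sets it near 0, left 4 higher and 6 lower precursors at 6 days. The 18 calls became 9 and 35 with an offset of 0.1 and of 1, 10 without the minimum, 1 after quantile normalization, 0 with the 4 libraries of 6 days fitted alone, and 1, 7, 4 and 7 without libraries 9, 10, 11 and 12. Without library 9 hsa-mir-210 was the call left. Without 1 library the calls of hsa-mir-182, hsa-mir-30b, hsa-mir-29b-2, hsa-mir-30d and hsa-mir-21 ended (adjusted p up to 0.163). The 1 call at 48 hr became 0 with its 4 libraries alone and 2 without library 5.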

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

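Among the tests of explanations, the one of short RNAs by class, the one of library scaling at 6 hr and the splits within each time were chosen only after the result was seen.

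The effect of hypoxia differed between times by limma's test of the difference in 63 genes from 6 hr to 48 hr, in 1276 from 48 hr to 6 days and in 2555 from 6 hr to 6 days. Differences are in log2 units, the later minus the earlier effect. From 6 hr to 48 hr they were 2.73 for TXNIP, 2.63 for CA9, 2.03 for NPPB, 1.66 for ARRDC4, 1.52 for KISS1R, 0.67 for PDK1 and -0.88 for PLA2G4A. The calls of PDK1 and PLA2G4A ended with any 1 of libraries 3 to 12 left out. That of PDK1 also ended without library 1. Libraries 9 to 12 are those of 6 days, which this difference does not use. In these fits the difference stayed at 0.59 to 0.68 for PDK1 and at -0.92 to -0.83 for PLA2G4A.

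From 48 hr to 6 days the differences were 3.05 for STC1, 2.48 for NPPB, 2.23 for TFRC, 1.99 for NPR3, 1.94 for LOX, 1.89 for NDRG1, 0.92 for CA9, 0.86 for ADM and 0.57 for BNIP3. They were -2.03 for DDIT4, -1.92 for CHAC1, -1.69 for HIST1H4I, -1.54 for TXNIP, -1.54 for ARHGAP4 and -0.46 for PDK1. For CA9 the direction rests on the offset: it was at 3.81 against 0.0149 RPKM at 48 hr and at 8.16 against 0.0535 RPKM at 6 days, a lower ratio, and with an offset of 0.1 its call ended (0.69, adjusted p = 0.246). With 1 library left out, the call of PDK1 ended for any of libraries 3 to 12 and that of BNIP3 for any of libraries 5 to 12. That of CA9 ended without library 5, 6, 8, 9, 10 or 12, and that of ADM without library 8.

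From 6 hr to 6 days the differences were 4.50 for NPPB, 3.56 for STC1, 3.55 for CA9, 3.24 for TFRC, 2.92 for LOX, 2.45 for NDRG1, 1.13 for BNIP3 and 0.90 for ADM. They were -2.40 for HIST1H4I, -2.20 for MTRNR2L7, -2.06 for MTRNR2L10, -1.95 for MTRNR2L6 and -1.94 for MTRNR2L2. The median log2 fold change of the MTRNR2L genes was 0.40 at 6 hr and -0.92 at 48 hr.

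The MTRNR2L genes were lower in hypoxia at 48 hr and 6 days. A single factor per library was excluded as the cause, since the median log2 fold change at 6 days was -1.48 as deposited and -1.54 after trimmed-mean centring. After quantile normalization it was -1.62. Their deviations from the group means moved together over the 12 libraries, with a median Pearson r of 0.8 over 45 pairs of 10 genes (range 0.000124 to 0.985). That is consistent with reads shared between near-identical copies, so the 10 values may stand for fewer independent ones. A loss of mitochondrial ribosomal RNA in hypoxia, of which these genes are copies, could give the same fall and was not tested.

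Short RNAs were higher in hypoxia at 6 days in every class with at least 5 genes, the lowest median log2 fold change being 0.54 (SNORA). A single factor per library was not the whole cause, with a median of 0.67 over 495 genes after trimmed-mean centring. Centring moves all genes of a library alike, and the median of all genes was already 0.04 as deposited, so it could lower this value little. Scaling that depends on level was not excluded by it. Quantile normalization lowered SNORD to 0.41, SCARNA to 0.43 and SNORA to 0.10. Noise of genes with few reads was excluded by a median of 0.64 over the 251 genes with a mean of at least 100 RPKM. Also open are a real gain of short RNAs and a difference between libraries in how much short RNA was taken. The latter could act on all classes alike. The 2 normoxia libraries of 48 hr alone differed in summed SNORD level, 468190 against 315730 RPKM, by as much as the groups of 6 days, 506760 against 380250 RPKM. The 4 RNU genes, too few for the test, had a median of 0.05.

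At 6 hr more genes were called higher than lower, 94.4% of 428. After trimmed-mean centring 76.6% were higher and after quantile normalization 76.1%, so part of the asymmetry moved with scaling and part stayed. The bounds for library scaling were set after the result was seen, so scaling was not judged by them. Centring was not combined with leaving out library 2. Without library 2, of the pair that stood furthest apart, 78.7% were higher, so that library could not be the whole cause. Repression that builds up later than induction stays open: after centring, genes lower at 48 hr had reached 0.362 of their change at 6 hr and genes higher at 48 hr 0.452, a ratio of 0.8 that meets neither bound set for it.

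For genes across times, splits parted the 4 libraries of each time 2 and 2. Of these, 1 of 100, the real one, called as many as the real 2681, the highest other calling 1545. That argues against chance spread between single libraries. Chance differences between cultures are not excluded, since the labels do not say whether the libraries of a group came from separate cultures. For precursors chance cannot be excluded, since 5 of 100 such splits, the real one included, called as many as the real 4, the highest other calling 7. Splits of all 12 libraries into 6 and 6 do not keep times balanced, and chance is not judged by them. As many were called in 2 of 100 for genes (highest other 3750) and in 4 of 100 for precursors (highest other 26). In both tables the highest of these set libraries 1, 2, 3, 4, 9 and 10 against the rest. With time as a term it compares normoxia with hypoxia at 6 days alone, where calls were most numerous, so it points to the structure of the samples.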

How the results depend on the processing

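The alternatives without the libraries of 6 days, and trimmed-mean centring for the lists, were chosen only after the results were seen. Directions of the 441 calls of named genes and precursors held under each alternative, and the number of these past the threshold was 436 with an offset of 0.1, 437 with an offset of 1, 408 with no minimum, 425 with quantile normalization, 435 with trimmed-mean centring and 432 without the intensity trend. It was 396 of 396 with a minimum of 5 RPKM, 249 of 275 with the 4 libraries of a time alone, and 7 of 7 without the libraries of 6 days. For precursors at 6 days, calls were 9 with an offset of 0.1, 35 with an offset of 1, 10 with no minimum, 1 with quantile normalization, 10 with trimmed-mean centring and 0 with the 4 libraries of that time, against 18. Across times the 4 precursor calls became 2 with no minimum, quantile normalization, trimmed-mean centring or no intensity trend, and 1 without the libraries of 6 days, where genes fell from 2681 to 1190. The 1 precursor call at 48 hr became 0 with its 4 libraries alone. Calls of the difference from 6 hr to 48 hr were 31 with no minimum and 97 with trimmed-mean centring, against 63, and from 48 hr to 6 days 2479 with quantile normalization, against 1276. Calls at 6 hr were 278 with the 4 libraries of that time, against 428, while those at 48 hr were 1977 against 1448 and those at 6 days 5368 against 5039. Normoxia at 48 hr against 6 hr gave 31 calls with a minimum of 5 RPKM, against 11. With an estimated correlation, lists past the threshold were 3, 5 and 0 at 6 hr, 48 hr and 6 days, against 12, 19 and 16. The cause was not tested.

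Some values near 0, none past the threshold, reversed. HIF1A at 6 hr, 0.02, was -0.03 with quantile normalization and with trimmed-mean centring. The difference for SLC2A1 from 48 hr to 6 days, -0.13, was 0.1 with quantile normalization, and that from 6 hr to 6 days, 0 when rounded, was 0 on the other side with trimmed-mean centring. The cause was not tested.

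Leaving out each of the 12 libraries in turn assumes that the lone library of a group varies like the other groups. Some of the named calls counted above ended at each time when 1 library was left out, including some not listed in the results. Calls ranged from 181 to 836 at 6 hr, 619 to 2066 at 48 hr, 3423 to 5797 at 6 days and 1861 to 3204 across times. For precursors they ranged from 1 to 2 at 48 hr, 1 to 27 at 6 days and 2 to 11 across times, and were 0 at 6 hr without each library. For the differences they ranged from 11 to 110 (6 hr to 48 hr), 365 to 2154 (48 hr to 6 days) and 1498 to 3147 (6 hr to 6 days). Normoxia at 48 hr against 6 hr gave 6 to 1310 calls, and at 6 days 5480 to 6716. Genes shared in the same direction ranged from 168 to 463 (6 hr and 48 hr), 518 to 1443 (48 hr and 6 days) and 170 to 524 (6 hr and 6 days). Among values that reversed, ADM (difference from 6 hr to 48 hr) ranged from -0.08 to 0.16, HIF1A (difference from 6 hr to 48 hr) ranged from -0.49 to 0.11, HIF1A at 48 hr ranged from -0.34 to 0, HIF1A at 6 hr ranged from -0.28 to 0.32, SLC2A1 (difference from 6 hr to 6 days) ranged from -0.08 to 0.09, VEGFA (difference from 6 hr to 48 hr) ranged from -0.09 to 0.21, hsa-mir-21 at 6 hr ranged from -0.44 to 0 and hsa-mir-675 at 6 hr ranged from -1.17 to 0.72, none of them past the threshold. No paired analysis was possible because the replicate numbers of the hypoxia and normoxia groups are not shared and the labels pair no libraries.

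Depth limits the precursors: at 25.2 to 51.8 M reads, 1 read on a precursor of 90 bases is 0.442 to 0.214 RPKM.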

Other observations

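Tests reported here were written before their results were seen.

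TFRC, whose RNA responds to iron supply in many cells, was singled out after its values were seen, as were the families that follow. In normoxia it was at 92.03 ± 14.7 RPKM at 6 hr, 94.98 ± 0.507 at 48 hr and 12.8 ± 0.502 at 6 days, and in hypoxia at 55.4 ± 0.287, 116.6 ± 7.04 and 76.2 ± 0.547 RPKM. The higher value in hypoxia at 6 days thus goes with a normoxia level that had fallen. The difference of the effect from 6 hr to 6 days was 3.24 on the log2 scale.

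Metallothioneins, which bind zinc and copper, had 3 tested members, and 3 were higher in hypoxia at 6 days, with a median log2 fold change of 0.95. Their summed level was 6.66 RPKM in normoxia and 13.9 RPKM in hypoxia at 6 days, against 17.02 and 18.3 RPKM at 6 hr. The small NF90-associated RNAs summed to 12359, 11804 and 1651 RPKM in normoxia at 6 hr, 48 hr and 6 days, and to 10163, 12585 and 2356 RPKM in hypoxia. Of 27 members 18 were higher in hypoxia at 6 days. Copies of this family can share reads.

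Genes lower in hypoxia at 48 hr may reach their change later than genes that are higher. As deposited, the 345 lower genes had reached 0.289 of their 48 hr change at 6 hr and the 1103 higher genes 0.515. After trimmed-mean centring the shares were 0.362 of 752 and 0.452 of 1156, a ratio of 0.8, which lies between the bounds set for and against this hypothesis, so it stays undecided.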
